A study of Mus musculus with 8 samples.

How the data were processed

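RNA was measured in 8 libraries from bone marrow of wild-type C57BL/6 mice, 2 from each of 4 sorted populations of common myeloid progenitors, the bone marrow cells that give rise to the granulocyte, monocyte, erythroid and megakaryocyte lineages. Per the labels, every population was positive for the receptor KIT and negative for the Fc receptors CD16/32. The CD34bright population was also CD41+ CD9+. The CD48dim and CD48bright populations were CD34dim CD41+ CD9+ and were parted by CD48. The last population was CD34dim and negative for CD41 and CD9, and is called CD41/CD9-negative here. Samples were grouped by these sort gates. The cluster numbers in the sample titles differ from those in the series' design text, and were not used. Nothing in the labels says that the 2 libraries of a population came from separate mice or sorts, so the p-values measure only the spread between these libraries, which may be technical.

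Per the labels' protocols, total RNA was taken up with Trizol and a spin column kit, 5 ng was amplified to cDNA with the Ovation RNA-Seq System V2, and 1 ug of cDNA entered a TruSeq stranded kit and was sequenced on an Illumina NovaSeq. Per the labels' protocols the libraries carry no strand information because of the amplification, so reads of overlapping and antisense genes cannot be told apart. Of 65 genes named by rule, 9 overlap another gene of the files. For Rag2 and Itga1 the overlapping genes Iftap (2716 counts against 2723) and Pelo (1528 against 906) had counts of a similar size, so their levels are uncertain. Members of close gene families (Ifi205, the haemoglobin genes, Fcgr3 and Fcgr2b, Ly6a, the major histocompatibility genes) can share reads that the estimation divides, and are uncertain in the same way.

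The deposited values used here are expected counts per gene, which need not be whole numbers, per the file headers in the layout of RSEM. STAR 2.7.2a, RSEM 1.3.2, edgeR 3.30.3 and the mouse build mm10 are named in the submitters' processing notes. Alignment settings, trimming and the annotation release are not given in the sources used here. The deposited tables hold 24411 genes with their effective lengths in bases, per the file headers, which were used only in an alternative with a length offset. A deposited second table per library holds the same expected counts for a subset of these genes, of which 9916 were tested and which took 83.1% of all counts, with a largest difference of 0. How those genes were chosen is not given in the sources used here. No mitochondrially encoded genes appear among the genes used here.

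Expected counts were rounded to whole numbers (up to 2.2% of genes per library were not whole). Of the 24411 genes, 18488 had a count and 13177 passed filterByExpr of edgeR 4.0.16 by population. Libraries were scaled by TMM, and levels are given as CPM, counts relative to the scaled library total, as mean ± SD over 2 libraries. Differences were tested with edgeR's quasi-likelihood F-test (glmQLFit after estimateDisp) in 1 model with a mean per population, 4 residual degrees of freedom and 5.46 prior degrees of freedom. All 8 libraries shared the spread estimate (biological coefficient of variation 49.8%). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of F, an approximation. All p-values are two-sided. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

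The comparisons were CD48bright against CD48dim, CD41/CD9-negative against the unweighted mean (on the log2 scale) of CD48dim and CD48bright, CD34bright against that same mean, any difference among the 4 populations, and the other pairs as counts of genes. Comparisons that share libraries are not independent, and their calls were not compared with one another. Before the data were examined, 20 gene lists (367 entries, some genes in more than 1 list), the rule for named genes, and the alternatives listed as planned were fixed. The rule named the 7 genes of the sort markers, the 10 called protein-coding genes with the largest log2 fold change in each direction (mean of at least 8 CPM, libraries of the 2 sides not overlapping), and up to 4 called members per list. Other list members are named with their values. Some genes that the rule names are not reported here. Lists with at least 5 tested members were tested in the 3 main comparisons with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 60 pairs of list and comparison, then with an estimated correlation and with fry. Of 36 pairs called with the preset correlation, 7 were called with an estimated one: the stem list in the CD48 and CD41/CD9 comparisons, the lymphoid list in the CD41/CD9 comparison, the monocyte and dendritic list in both, and the mitosis list in the CD48 and CD34 comparisons. Gene positions and biotypes are those of GRCm38.p6, the same assembly as mm10, and 23194 symbols matched it directly and 1124 through transcript identifiers. The list genes Ighm, Ahsp, Iglc2, Trac, Trbc2 and Ly6g were not analysed here.

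Library totals ran from 7237587 to 20632005 counts. A population at 0 counts was set to a floor of 3 counts over its 2 libraries together, 0.0897 CPM in CD34bright, 0.144 CPM in CD48dim, 0.0995 CPM in CD48bright and 0.12 CPM in CD41/CD9-negative. Reads after amplification are not independent molecules, so such floors cover counting error only. The fitted fold change of a gene with 3 counts or fewer in a population depends on the prior count, and levels are given in its place. With these genes at their bound, the median log2 fold change moved by over 0.1 in 4 of the 60 pairs of list and comparison.

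The test was tried on simulated counts in which 100 genes were changed 4-fold and 100 changed 16-fold. The changed genes were drawn only from those with a mean of at least 8 CPM. These counts had the mean of each gene over all 8 libraries, the library sizes, and 1 spread per gene shared by all populations. The larger spread within CD48dim was not simulated, so the figures hold only for an equal spread and for genes of at least 8 CPM. At 4-fold, 39% were recovered for CD48bright against CD48dim, 67% for the CD41/CD9 comparison, 55% for the CD34 comparison and 40% for CD34bright against CD48bright. At 16-fold, 92%, 97%, 94% and 97% were recovered, and 7 to 10 unchanged genes were called, of 12680 to 12723 tested. In each simulated comparison 0 of 20 unchanged lists and 20 of 20 changed lists were called. Simulated genes varied independently of one another, while the estimated correlation within a real list reached 0.794. Most members of a changed list were raised 4-fold or 16-fold. These list results therefore do not test the preset correlation. The alternatives were other size factors, no or a stricter count filter, DESeq2, limma-voom, a length offset, removal of ribosomal RNA and haemoglobin genes, a fit of the compared libraries alone, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were the authors' gene subset, another quasi-likelihood setting, voom with quality weights, and removal of both CD48dim libraries.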

Results

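Gene expression was measured in 4 populations of mouse common myeloid progenitors separated by surface CD34, CD41, CD9 and CD48, with 2 libraries each. The populations come from a study that defined them by single-cell clustering, and the comparisons ask which genes part the sorted fractions. The libraries held 20632005 and 15017611 expected counts for CD34bright, 12753193 and 7237587 for CD48dim, 19594630 and 10318447 for CD48bright, and 12893841 and 12073092 for the CD41/CD9-negative population. Of 24411 genes, 13177 were tested.

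The genes of the sort markers followed the gates in part. Itga2b, which encodes CD41 (chromosome 11, 102453297 to 102469883), lay at 2.51 ± 0.462 CPM (SD, n = 2) in CD41/CD9-negative cells, against 133.7 ± 30.4 in CD48dim, 79.0 ± 20.9 in CD48bright and 89.9 ± 20.1 in CD34bright. Cd48 (chromosome 1, 171681245 to 171705258) lay at 26.4 ± 13.4 CPM in CD48dim and 203.9 ± 35.5 in CD48bright, with 182.8 ± 37.1 in CD34bright and 233.5 ± 17.5 in CD41/CD9-negative cells. Cd9 was at 7.43 ± 6.5 CPM in the CD41/CD9-negative population and between 40.1 and 48.8 CPM in the others, but its log2 fold change of -2.45 ± 0.62 (SE) did not pass (adjusted p = 0.0864, edgeR). Cd34 (chromosome 1, 194938821 to 194961292) was at 485.1 ± 34.7 CPM in CD34bright against 181.3 ± 21.9, 315.3 ± 116 and 317.3 ± 111 CPM in CD48dim, CD48bright and CD41/CD9-negative cells, a log2 difference from the CD34dim CD41+ CD9+ mean of 1.02 ± 0.32 that did not pass (adjusted p = 0.448, edgeR). Fcgr3 and Fcgr2b, of the Fc receptors CD16 and CD32, were read in all 4 populations although each was gated negative for CD16/32, at means of 10.9 to 55 CPM for Fcgr3 (87.3 in CD48bright replicate 1 and 3.02 in CD48dim replicate 2) and 17.3 to 36.2 CPM for Fcgr2b, and neither passed in the 3 main comparisons. Kit, the gene of the receptor that all populations were sorted on, ranged from 299.1 ± 83.5 CPM in CD41/CD9-negative to 998.7 ± 322 CPM in CD48dim cells. With the replicate number as a block, 2 of the tests of these 7 genes that had not passed did pass, none of them in the CD34 comparison.

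**Figure D1:**
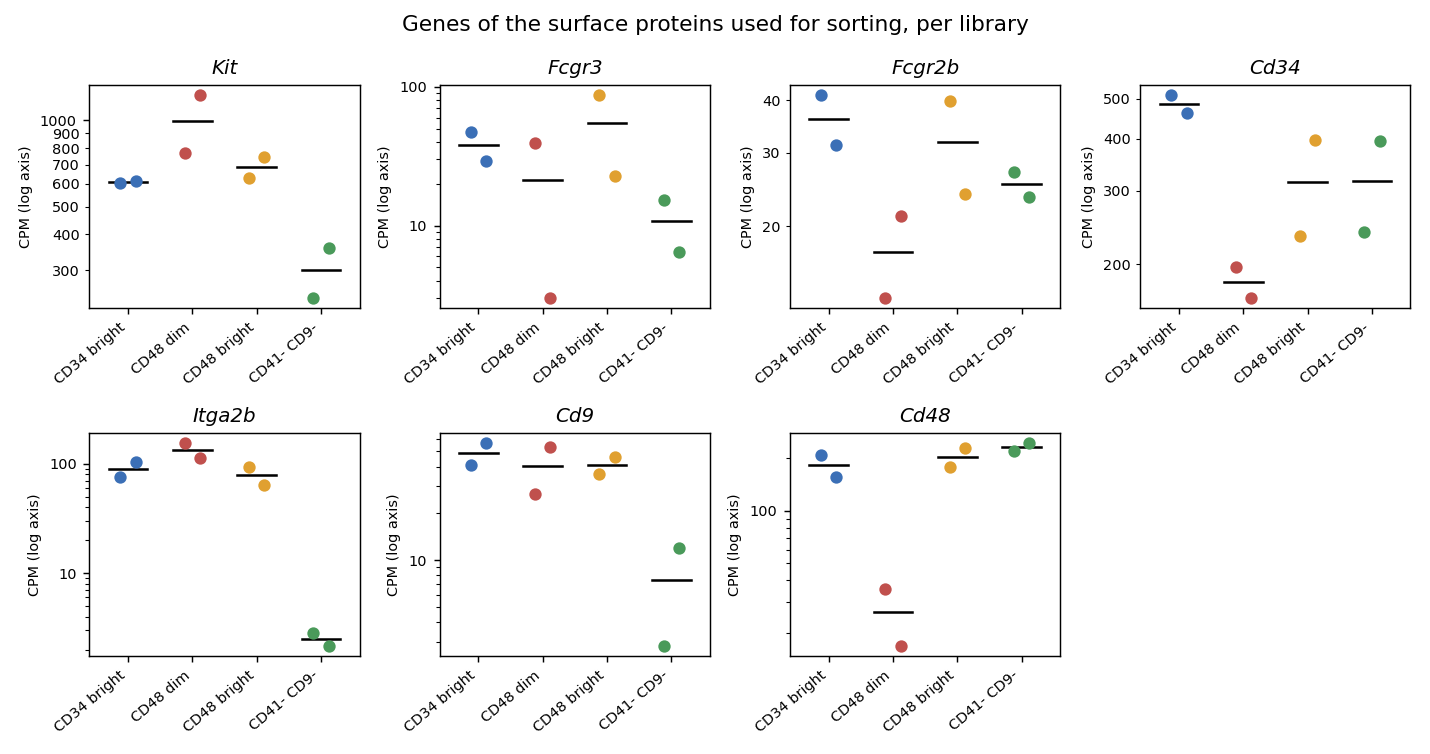
CPM on log axes for the 7 genes of the sort markers in 4 populations. Points are single libraries and lines the mean of 2 libraries; Itga2b is at 2.51 CPM in CD41/CD9-negative cells and Cd48 at 26.4 CPM in CD48dim cells.

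The CD48dim libraries stood apart from the rest and from each other. Over the tested genes the Spearman correlation between libraries of a population was 0.976 in CD34bright, 0.954 in CD48bright and 0.962 in CD41/CD9-negative, and 0.836 in CD48dim. CD34bright replicate 1 and CD48bright replicate 1 correlated at 0.981, above the pairs within each of the 4 populations. These correlations are across genes, which are not independent replicates. The nuclear RNA Malat1 reached 38918 CPM in CD48dim replicate 2, against 5003 to 14861 CPM elsewhere. The libraries also split by their replicate number, which was seen only after the values were examined. In each of the 4 populations the library numbered 2 had fewer counts, more Malat1 (11372 against 5003 CPM in CD34bright, 38918 against 10306 in CD48dim, 12334 against 7101 in CD48bright and 14861 against 9470 in CD41/CD9-negative) and a lower share of ribosomal protein genes (6.19% against 9.61%, 2.46% against 9.04%, 5.9% against 8.23% and 5.26% against 6.54%). What the numbers mark is not given in the sources used here. The unprocessed ribosomal RNA Rn45s took 0.79% to 9.93% of the counts. Transcripts of mature neutrophils (S100a8, S100a9, Ngp, Ltf and others of that list) summed to 4174 and 624 CPM in CD48dim, 702 and 49.9 CPM in CD41/CD9-negative, and 115 to 166 CPM in the other 4 libraries. Haemoglobin transcripts summed to 288 CPM in CD48dim replicate 1 and 6.96 to 53 CPM in the other 7 libraries.

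CD48bright cells were richer than CD48dim cells in the monocyte and dendritic genes and poorer in the stem cell genes, and single lymphoid and platelet genes also differed. Dntt, the terminal transferase of early lymphoid cells (chromosome 19, 41029275 to 41059525), lay at 69.1 ± 41.2 CPM in CD48bright and 1.12 ± 1.01 CPM in CD48dim, a log2 fold change of 5.81 ± 0.73 (adjusted p = 0.0216, edgeR). Irf8, a transcription factor of monocytes and dendritic cells (chromosome 8, 120736358 to 120756694), lay at 188.5 ± 26.4 against 3.55 ± 4.63 CPM (5.64 ± 0.92, adjusted p = 0.0453). Mecom, a transcription factor of stem cells (chromosome 3, 29951296 to 30509759), lay at 8.96 ± 2.85 against 89.95 ± 37 CPM (-3.32 ± 0.53, adjusted p = 0.0453). Altogether 51 genes were called, 36 higher and 15 lower in CD48bright.

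Siglech, Kmo, Ifi205 and Cd209a were at 0 counts in both CD48dim libraries. Siglech, a receptor of plasmacytoid dendritic cells, lay at 17.2 ± 11.1 CPM in CD48bright, at least 120-fold above the floor, and Kmo, an enzyme of tryptophan breakdown, at 20.4 ± 2.58 CPM, at least 142-fold. Ifi205 and Cd209a lay at 30.1 ± 8.33 and 20.4 ± 0.00239 CPM in CD48bright. The integrin gene Itgax and the surface marker gene Ly6d lay at 23.2 ± 5.73 and 11.6 ± 5.44 CPM, each with 0.0734 CPM in CD48dim. On the other side, the prostaglandin transporter gene Slco2a1 was at 55.6 ± 37.8 CPM in CD48dim against 0.0457 CPM in CD48bright, Nbea at 41.6 ± 21.1 against 0.716 ± 0.237 CPM, and the proteoglycan gene Bgn at 112.7 ± 32.4 against 5.34 ± 0.339 CPM. Procr, the protein C receptor of stem cells, lay at 51.1 ± 4.74 against 2.87 ± 0.95 CPM (-4.14 ± 0.68, adjusted p = 0.0453). The largest negative changes also held Palld, Camsap3, Plxdc2, Zfp532 and Mmrn1, a platelet granule protein, with log2 fold changes of -3.37 to -4.32.

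Of the 20 monocyte and dendritic genes, 6 rose and 0 fell over all genes tested, and 16 rose adjusted over the list alone, with a median log2 fold change of 2.79 (camera adjusted p = 4.70e-28, and adjusted p = 0.021 with an estimated correlation). All 20 stem cell genes had a negative sign, 2 fell over all genes and 11 adjusted over the list alone, with a median of -2.25 (camera adjusted p = 3.69e-15, and adjusted p = 0.0179 with an estimated correlation). Of 24 mitosis genes, 22 had a positive sign, 0 passed over all genes and 14 rose adjusted over the list alone, among them Cdk1 (1.65) and Ccna2 (1.72), with a median of 1.03 (camera adjusted p = 1.10e-10, and adjusted p = 0.0207 with an estimated correlation). Of the 13 lymphoid genes, Dntt and Il7r rose over all genes and 5 adjusted over the list alone (camera adjusted p = 1.97e-09, but adjusted p = 0.13 with an estimated correlation). Of 23 megakaryocyte and platelet genes, 2 fell over all genes and 6 adjusted over the list alone, where 1 rose (camera adjusted p = 2.88e-07, but adjusted p = 0.14 with an estimated correlation). Of 20 interferon genes, 0 passed over all genes and 6 fell adjusted over the list alone, among them Isg15 (-3.68) and Ifi44 (-2.98) (camera adjusted p = 0.000484, but adjusted p = 0.13 with an estimated correlation), and without CD48dim replicate 1 the list was not called (median -0.15 against -0.83, camera adjusted p = 0.0643). The interferon median was -1.503 without CD48dim replicate 2 and -1.45 without CD48bright replicate 1. Of 10 mature neutrophil genes, 8 fell and 1 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 5.45e-06, but adjusted p = 0.279 with an estimated correlation).

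The number of genes called between CD48bright and CD48dim varied with the test and with the libraries in the fit. DESeq2 called 759 genes and limma-voom 5, and an edgeR fit of these 4 libraries alone called 0, with 931 genes at an unadjusted p below 0.05 against 1920 in the fit of all 8. With the replicate number as a block edgeR called 178 genes, including all 51. Without CD48dim replicate 1 edgeR called 3211 genes and without replicate 2 it called 412, both including all 51, and without another library it called 21 (CD34bright replicate 1), 21 (CD34bright replicate 2), 12 (CD48bright replicate 1), 4 (CD48bright replicate 2), 8 (CD41/CD9-negative replicate 1) or 8 (CD41/CD9-negative replicate 2). Leaving out a CD48dim library takes the spread within CD48dim out of the estimate, so the higher counts in those fits do not bear out the 51 calls. Of the 25 called genes named by rule, 25 stayed called with DESeq2, 3 with limma-voom and 1 with voom with quality weights. In the edgeR fit of these 4 libraries alone 0 stayed called. All 25 kept their sign in these fits and with each library left out in turn. The gene lists were not tested in fits of the compared libraries alone. In such fits the other pairs with CD48dim also lost calls, from 76 to 0 for CD34bright and 530 to 129 for CD41/CD9-negative. Against CD41/CD9-negative, calls rose from 111 to 1081 for CD34bright and 28 to 307 for CD48bright. CD34bright against CD48bright stayed at 0. Calls against CD48dim thus depended in part on the other populations, whose libraries were closer to each other.

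**Figure D2:**
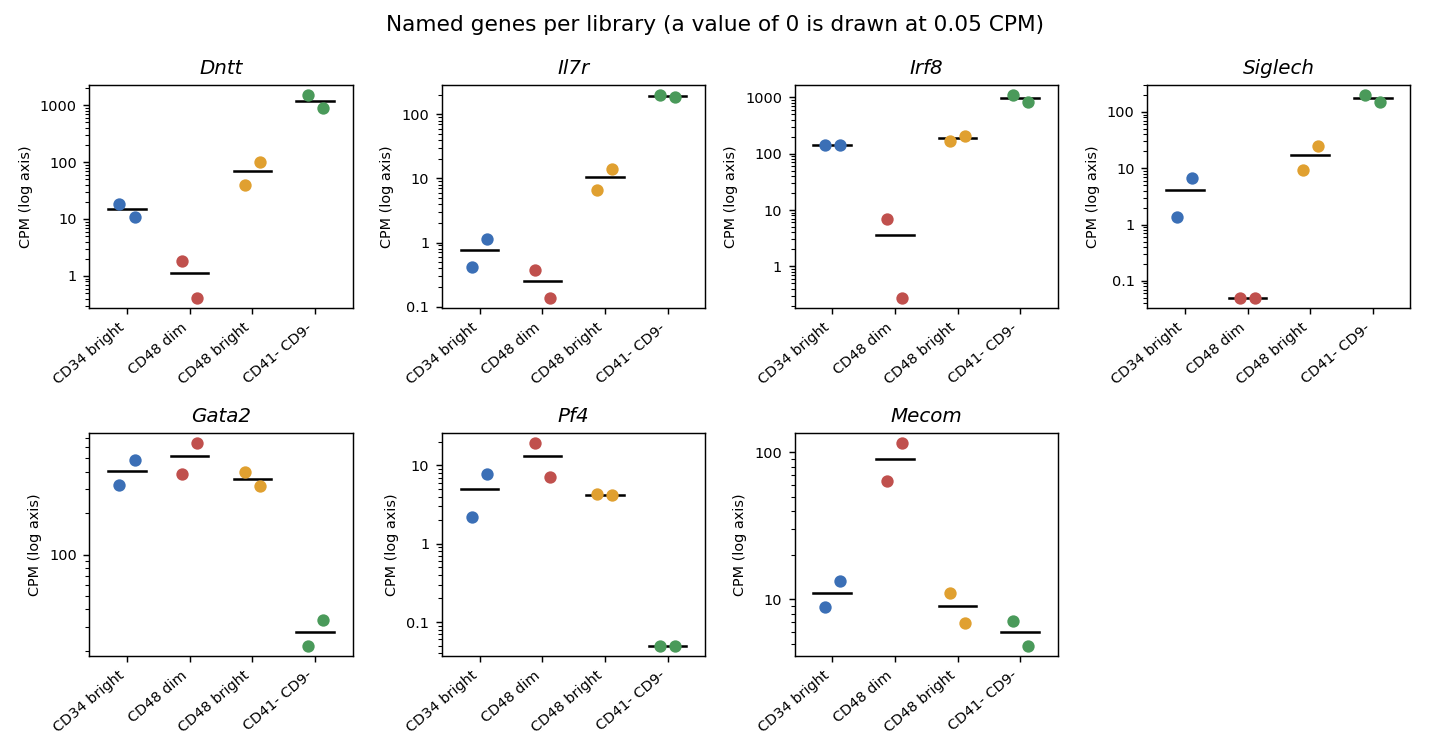
CPM on log axes for Dntt, Il7r, Irf8, Siglech, Gata2, Pf4 and Mecom in 4 populations, with single libraries as points and the mean of 2 libraries as a line. Dntt is at 1205 CPM and Irf8 at 962 CPM in CD41/CD9-negative cells, and Mecom at 89.95 CPM in CD48dim cells; a value of 0 is drawn at 0.05 CPM.

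CD41/CD9-negative cells differed from the CD34dim CD41+ CD9+ mean in lymphoid and in monocyte and dendritic genes, which were higher. They also differed from it in stem cell genes, which were lower. Single platelet and mast cell genes also fell, while the lists they belong to were not called with an estimated correlation (adjusted p = 0.108 and 0.0506). Dntt reached 1205 ± 422 CPM (log2 fold change 7.03 ± 0.55, adjusted p = 0.00057, edgeR), and Il7r, the receptor for interleukin 7 (chromosome 15, 9506159 to 9529941), 193.3 ± 8.85 CPM against 0.252 ± 0.162 in CD48dim and 10.4 ± 5.15 in CD48bright (6.81 ± 0.50, adjusted p = 0.00057). Irf8 reached 962 ± 201 CPM (5.17 ± 0.67, adjusted p = 0.00601). Gata2, a transcription factor of stem, mast and megakaryocyte cells (chromosome 6, 88193891 to 88207032), was at 27.6 ± 8.11 CPM against 515.1 ± 185 in CD48dim and 353.8 ± 59.4 in CD48bright (-3.95 ± 0.42, adjusted p = 0.00225). In all, 322 genes were called, 202 higher and 120 lower.

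All 13 lymphoid genes had a positive sign, 11 rose over all genes tested and 13 adjusted over the list alone, with a median of 3.04 (camera adjusted p = 1.26e-51, and adjusted p = 0.0179 with an estimated correlation). Among them were the recombinase genes Rag1 (66.6 ± 0.525 CPM, log2 fold change 5.35) and Rag2 (92.7 ± 24 CPM, 6.60), the cytokine receptor gene Flt3 (487 ± 118 CPM), Satb1 (3.04) and Notch1 (2.17). Against CD48bright alone the lymphoid median was 2.77, and 4 of the 13 genes passed. Of 20 monocyte and dendritic genes, 10 rose and 0 fell over all genes and 14 rose adjusted over the list alone (camera adjusted p = 7.09e-31, and adjusted p = 0.0234 with an estimated correlation). The median of this list was 2.63, and 2.34 with 3 genes at their bound. Against CD48bright alone its median was 1.07, and 1 of the 20 genes passed. Siglech lay at 175.2 ± 34.1 CPM, at least 1221-fold above the floor of CD48dim, and Cx3cr1, the fractalkine receptor, at 43.4 ± 2.76 CPM against 0.0367 in CD48dim and 13.4 in CD48bright. The antigen presentation genes Cd74, H2-Aa and H2-Ab1 of the same list did not pass (0.64, 0.26 and -0.13). Of 11 B cell genes, 3 rose over all genes, among them Fcrla and Ebf1, and 5 adjusted over the list alone (camera adjusted p = 1.18e-08, but adjusted p = 0.072 with an estimated correlation). Ebf1 lay at 37.3 ± 7.72 CPM. Of 9 T and NK cell genes, Klrd1 and Lck rose, also adjusted over the list alone (camera adjusted p = 0.0033, but adjusted p = 0.225 with an estimated correlation), and without CD48dim replicate 2 the list was not called (median 1.48, camera adjusted p = 0.111). The median of the T and NK cell list was 1.41 with all libraries, 0.96 with 3 genes at their bound, 3.36 without CD48dim replicate 1 and 0.81 without CD41/CD9-negative replicate 1. Other genes with the largest increases were Kmo, Ctnnd2, Ly6d, Rasal1, Cox6a2 and Strip2, at 30.1 to 114 CPM, and the transferrin receptor gene Tfrc rose to 703.6 ± 133 CPM (2.28 ± 0.29, adjusted p = 0.00601).

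Of 23 megakaryocyte and platelet genes, 7 fell and 1 rose over all genes, and 9 fell and 1 rose adjusted over the list alone, with a median of -1.94 (camera adjusted p = 5.94e-11, but adjusted p = 0.108 with an estimated correlation). Pf4, platelet factor 4 (chromosome 5, 90772435 to 90773383), and Treml1 were at 0 counts in CD41/CD9-negative cells, against 13.3 ± 8.7 and 5.89 CPM in CD48dim, and Rab27b lay at 0.321 ± 0.231 CPM against 27.1 ± 0.564 and 11.2 ± 1.8. Of 15 basophil, eosinophil and mast cell genes, 4 fell over all genes (Fcer1a, Ms4a2, Gata2 and Hdc) and 9 adjusted over the list alone (camera adjusted p = 5.94e-11, but adjusted p = 0.0506 with an estimated correlation). Fcer1a, a subunit of the IgE receptor, lay at 0.119 ± 0.0542 CPM against 9.43 ± 9.4 in CD48dim and 44.1 ± 15.9 in CD48bright. Of the 20 stem cell genes, Esam, Tek, Procr and Mecom fell over all genes and 8 fell adjusted over the list alone, with a median of -1.60 (camera adjusted p = 5.94e-11, and adjusted p = 0.0207 with an estimated correlation). The stem list deviated from its mean over all libraries (log2) by -1.35 and -1.05 in CD41/CD9-negative cells. It deviated by -0.29 and -0.70 in CD48bright and by 1.93 and 1.72 in CD48dim, so its fall was larger against CD48dim. Of 32 haematopoietic transcription factors, Irf8 rose and 6 fell, among them Gata2, Zfpm1 (-2.94) and Tal1 (-2.35), and 2 rose and 12 fell adjusted over the list alone (camera adjusted p = 6.78e-07, but adjusted p = 0.0506 with an estimated correlation). Of 18 neutrophil granule genes, 0 passed over all genes and 8 fell adjusted over the list alone, among them Elane at 274.2 ± 1.42 CPM (camera adjusted p = 2.88e-07, but adjusted p = 0.296 with an estimated correlation). The granule list deviated by -0.74 and -1.18 in CD41/CD9-negative, 0.87 and -0.86 in CD48dim and 1.18 and -0.16 in CD48bright. CD48dim replicate 2 thus lay within the range of CD41/CD9-negative cells. The granule median of -1.54 was -0.85 without CD48dim replicate 1 and -1.03 without CD48bright replicate 1. Kcnj5, Sdpr and Cxcl12 were at 0 counts in CD41/CD9-negative cells, and Bgn, Clstn3, Tie1, Phldb2 and Pdzk1ip1 at 0.0394 to 0.752 CPM.

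DESeq2 called 901 genes for this comparison, including all 322, and an edgeR fit of the 6 libraries compared called 179. Limma-voom did not change the count by over 1.5 times, and with the replicate number as a block edgeR called 562, including all 322. The count was 1692 without CD48dim replicate 1, 1086 without CD48dim replicate 2, 29 and 56 without CD41/CD9-negative replicates 1 and 2, 102 and 139 without CD48bright replicates 1 and 2, and 211 without either CD34bright library. Of the 47 called genes named by rule, 47 stayed called with DESeq2, 34 with limma-voom and 41 with voom with quality weights. In the edgeR fit of the 6 libraries compared 36 stayed called. Their sign stayed the same in these fits and with each library left out in turn. Mature neutrophil genes did not pass in this comparison (camera adjusted p = 0.213), but their direction rested on single libraries. The median log2 fold change was -0.48 with all 8 libraries, -3.64 without CD41/CD9-negative replicate 1 (camera adjusted p = 1.70e-08), 0.39 without CD41/CD9-negative replicate 2 (adjusted p = 0.0369) and 0.95 without CD48dim replicate 1 (adjusted p = 0.734).

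**Figure D3:**
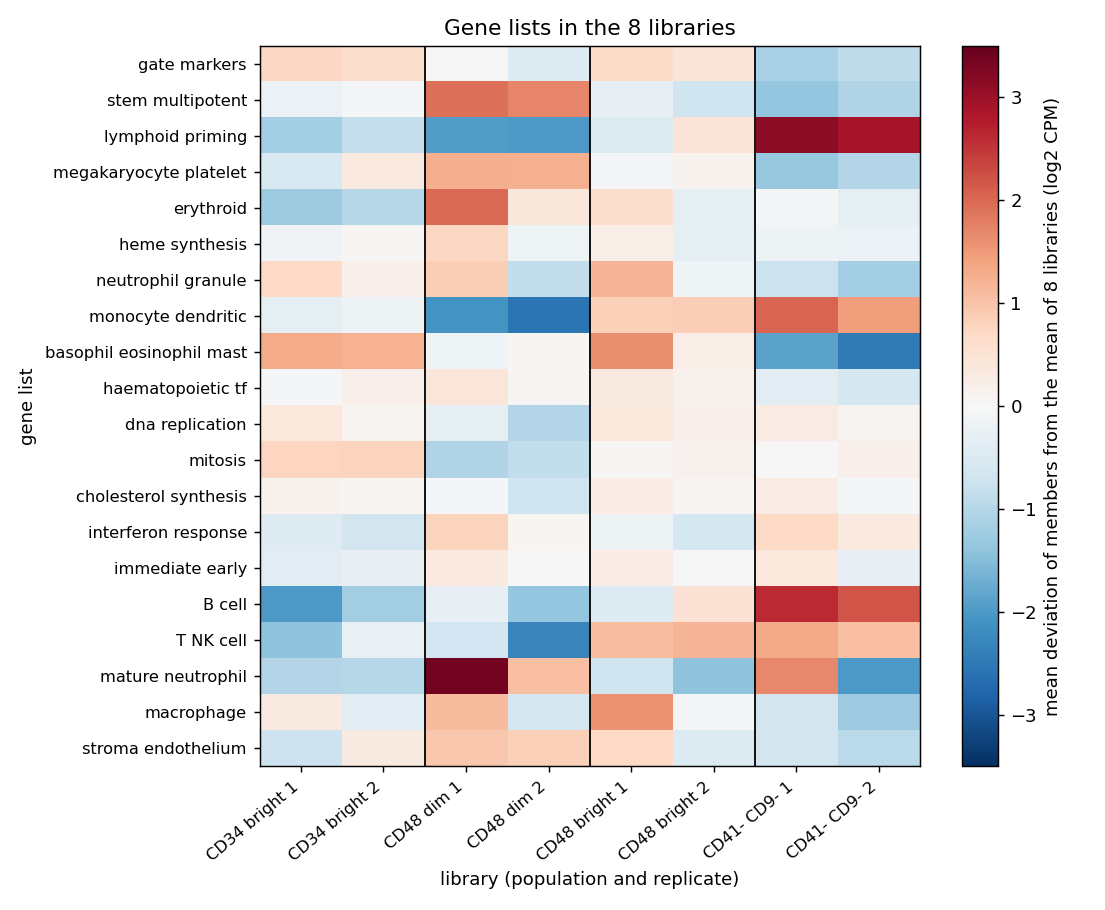
Mean deviation of the members of 20 gene lists from their mean over 8 libraries (log2 CPM, colour scale), with a column per library. Lymphoid genes deviate by 3.13 and 2.89 in the CD41/CD9-negative libraries, stem cell genes by 1.93 and 1.72 in CD48dim, and mature neutrophil genes by 3.38 in CD48dim replicate 1.

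CD34bright cells differed from the CD34dim CD41+ CD9+ mean in the genes of mitosis. All 24 mitosis genes had a positive sign, 17 of them rose adjusted over the list alone, with a median log2 fold change of 1.19 (camera adjusted p = 3.44e-29, and adjusted p = 0.0131 with an estimated correlation). Ccnb1, the mitotic cyclin B1, lay at 180.2 ± 1.4 CPM in CD34bright against 31.5 ± 5.05 in CD48dim and 73.2 ± 11.8 in CD48bright, and Ube2c at 242.5 ± 40.7 against 41.6 ± 24.1 and 91.5 ± 18.6 CPM. Of 30 erythroid genes, 29 had a negative sign, with a median of -2.10, and 10 fell adjusted over the list alone (camera adjusted p = 3.75e-17, but adjusted p = 0.108 with an estimated correlation). The size rested in part on CD48dim replicate 1, in which the list deviated by 1.995 from its mean over all libraries (log2) against 0.41 in CD48dim replicate 2, and without which the median was -1.45 (camera adjusted p = 2.28e-08). Car1, a carbonic anhydrase of red cell precursors, lay at 43.5 ± 11.8 CPM against 347 ± 14.7 in CD48dim and 311 ± 191 in CD48bright, and Ermap at 5.86 ± 2.97 against 83.9 ± 45 and 56.7 ± 30.4 CPM.

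Over all genes tested, 0 genes were called in this comparison by edgeR and by limma-voom, 1095 had an unadjusted p below 0.05, and DESeq2 called 241. The smallest adjusted p was 0.215. Of 20 monocyte and dendritic genes, 6 rose and 1 fell adjusted over the list alone, among them Csf1r, the receptor of macrophage colony-stimulating factor, at 61.4 ± 1.39 CPM against 3.73 ± 3.34 and 48.25 ± 3.65 (camera adjusted p = 0.000544, but adjusted p = 0.183 with an estimated correlation). As a whole this list lay between CD48dim and CD48bright in CD34bright cells. Its deviations from the mean over all libraries (log2) were -0.33 and -0.19 in CD34bright, 0.83 and 0.85 in CD48bright and -2.08 and -2.565 in CD48dim. Of 15 basophil, eosinophil and mast cell genes, 4 rose adjusted over the list alone, among them Cpa3, a mast cell protease (camera adjusted p = 0.000118, but adjusted p = 0.108 with an estimated correlation). This list deviated by 1.31 and 1.22 in CD34bright, 1.635 and 0.24 in CD48bright and -0.16 and 0.08 in CD48dim. Of the 20 stem cell genes 17 had a negative sign and 0 passed (camera adjusted p = 0.000122, but adjusted p = 0.0654 with an estimated correlation). The stem list in CD34bright lay below CD48dim but not below CD48bright. It deviated by -0.20 and -0.06 in CD34bright, -0.29 and -0.70 in CD48bright and 1.93 and 1.72 in CD48dim. Cd34 and Cd48 passed adjusted over the list alone among the 7 sort marker genes. Leaving out CD48dim replicate 1 raised the count of called genes from 0 to 1621, and leaving out CD48dim replicate 2 raised it to 165. Without any of the other 6 libraries edgeR called 0 genes, with 384 to 990 at an unadjusted p below 0.05.

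Across the 4 populations 322 genes differed. The highest mean lay in CD41/CD9-negative cells for 155 of them, in CD48dim for 134, in CD34bright for 25 and in CD48bright for 8. Leaving out a library changed this count to 168 and 169 (CD34bright replicates 1 and 2), 3399 and 1287 (CD48dim), 205 and 195 (CD48bright) and 32 and 48 (CD41/CD9-negative). Between pairs, CD41/CD9-negative against CD48dim gave 530 genes, with 261 higher and 269 lower. CD34bright against CD41/CD9-negative gave 111, with 35 higher and 76 lower. CD34bright against CD48dim gave 76, with 48 higher and 28 lower, and CD41/CD9-negative against CD48bright gave 28, with 11 higher and 17 lower. With the replicate number as a block edgeR called 764 genes across the 4 populations, and 965, 266, 682 and 99 genes for these 4 pairs in the same order, including all genes called without it. Leaving out replicates 1 and 2 of CD34bright, CD48dim, CD48bright and CD41/CD9-negative in turn moved these 4 counts. CD41/CD9-negative against CD48dim gave 297, 280, 3295, 1466, 348, 334, 81 and 106 genes. CD34bright against CD41/CD9-negative gave 9, 5, 749, 772, 67, 64, 3 and 9. CD34bright against CD48dim gave 0, 3, 3911, 684, 35, 31, 0 and 0, and CD41/CD9-negative against CD48bright gave 8, 8, 425, 435, 0, 1, 0 and 0. Between CD34bright and CD48bright edgeR and limma-voom called 0 genes, with 262 at an unadjusted p below 0.05 where chance alone gives 659, and DESeq2 called 37. Without CD48dim replicate 1 edgeR called 17 genes for this pair and without replicate 2 it called 20. In simulated data for that pair, with an equal spread in all populations, edgeR recovered 40% of 4-fold and 97% of 16-fold changes. These changes were simulated only in genes with a mean of at least 8 CPM.

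**Figure D4:**
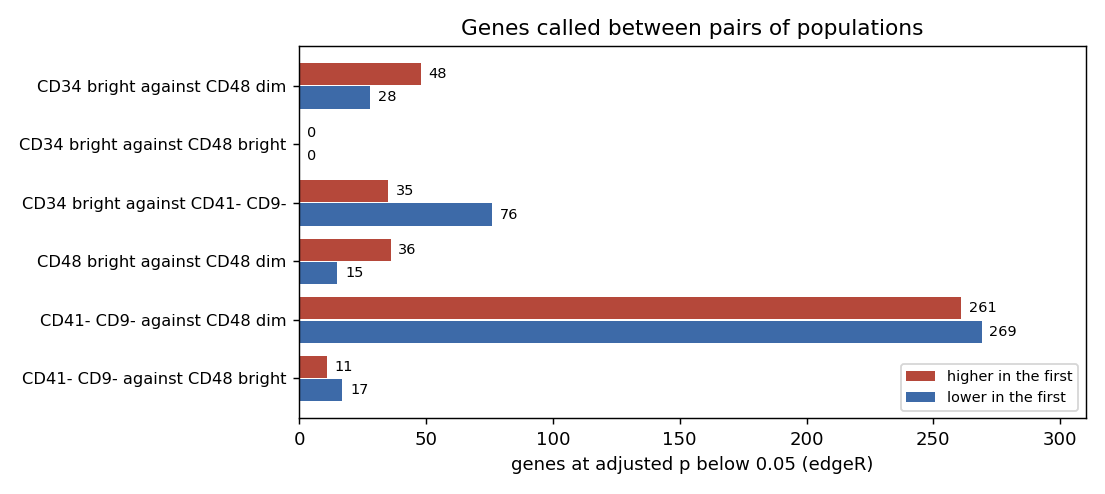
Number of genes called by edgeR at an adjusted p below 0.05 for 6 pairs of populations, with genes higher in the first population in red and lower in blue. CD41/CD9-negative against CD48dim gave 261 and 269 genes, and CD34bright against CD48bright 0 and 0.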

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

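The authors' gene subset, the other quasi-likelihood setting, voom with quality weights and the removal of both CD48dim libraries were chosen after the data were seen. With 2 libraries per population, leaving out 1 leaves a lone sample that is assumed to vary like the other groups. Higher counts without a CD48dim library therefore do not bear out the calls made with it. The planned quasi-likelihood setting equals the installed default and gave no separate value. Other size factors and the removal of ribosomal RNA and haemoglobin genes kept every count within 1.5 times. Of the settings run, the median log2 change of all genes lay beyond 0.1 only without CD48dim replicate 1, at 0.18 in the CD48 and 0.11 in the CD41/CD9 comparison. For the counts below the cause was not tested.

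Called genes are given for the 4 populations together, CD48bright against CD48dim, the CD41/CD9 comparison, the CD34 comparison, CD34bright against CD48dim, CD48bright and CD41/CD9-negative, and CD41/CD9-negative against CD48dim and CD48bright, in this order. Without a count filter they were 1607, 588, 778, 206, 1018, 39, 532, 1191 and 301. With DESeq2 they were 1718, 759, 901, 241, 1288, 37, 624, 1536 and 366. Leaving out 1 library gave 32 to 3399, 4 to 3211, 29 to 1692, 0 to 1621, 0 to 3911, 0 to 20, 3 to 772, 81 to 3295 and 0 to 435.

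The replicate number as a block gave 764 genes for the 4 populations, 178 for CD48, 562 for CD41/CD9, 682 for CD34bright against CD48dim, 266 for CD34bright against CD41/CD9-negative, and 965 and 99 for CD41/CD9-negative against CD48dim and CD48bright. The numbers are not stated to pair the samples, although deviations of libraries with the same number correlated by 0.112 to 0.222 in the 6 pairs of populations. The other quasi-likelihood setting gave 753, 104, 491, 309, 254, 819 and 88 for the same 7 counts. Voom with quality weights gave 1100 for the 4 populations, 2 for CD48, 7 for CD34, 15 and 926 for CD34bright against CD48bright and CD41/CD9-negative, and 188 and 300 for CD41/CD9-negative against CD48dim and CD48bright. Plain limma-voom gave 5 for CD48 and 45 for CD34bright against CD48dim.

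An edgeR fit of the compared libraries alone gave 0 for CD48 (931 genes at an unadjusted p below 0.05), 0 for CD34bright against CD48dim (1572), 179 for CD41/CD9, 1081 for CD34bright against CD41/CD9-negative, and 129 and 307 for CD41/CD9-negative against CD48dim and CD48bright. For this last pair a stricter count filter gave 14, a length offset 14 and the authors' gene subset 12. Without both CD48dim libraries the counts were 12 and 725 for CD34bright against CD48bright and CD41/CD9-negative, and 380 for CD41/CD9-negative against CD48bright. Of 60 pairs of list and comparison, 36 passed camera with the preset correlation, 7 with an estimated one and 18 with fry, and 33 to 43 with 1 library left out. The median of the mature neutrophil list in the CD41/CD9 comparison turned from -0.48 to 0.39 without CD41/CD9-negative replicate 2, and ranged from -3.64 without CD41/CD9-negative replicate 1 to 0.95 without CD48dim replicate 1.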

Other observations

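The tests of admixture and of the CD48dim spread on CD34bright against CD48bright were chosen after the values were seen. The tests of depth and of lost transcripts in CD48dim replicate 2 were set before their results were seen.

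Lists of proliferation and interferon genes, which no sort marker names, gave the following values. Of 24 DNA replication genes, 23 had a positive sign in CD48bright against CD48dim, with 7 rising adjusted over the list alone and a median log2 fold change of 0.92 (camera adjusted p = 2.88e-07, but adjusted p = 0.153 with an estimated correlation). The median was 1.42 without CD48dim replicate 1 and 0.65 without CD48dim replicate 2. Against the CD34dim CD41+ CD9+ mean, 21 of 24 mitosis genes had a positive sign in CD41/CD9-negative cells, with 0 passing over all genes in edgeR or adjusted over the list alone (median 0.53, camera adjusted p = 0.000544, but adjusted p = 0.0756 with an estimated correlation). Cholesterol synthesis genes did not pass in the 3 main comparisons, with camera adjusted p = 0.204, 0.544 and 0.544, nor did haem synthesis genes (0.145, 0.135 and 0.286). The haem list passed without CD48dim replicate 2 (median -0.70) and CD48bright replicate 1 (-0.72) in CD48bright against CD48dim, and without CD48dim replicate 2 (-0.37) and CD48bright replicate 2 (-0.36) in the CD41/CD9 comparison. Of 20 interferon genes in CD34bright, 18 had a negative sign and 0 passed over all genes in edgeR or adjusted over the list alone (camera adjusted p = 0.00102, but adjusted p = 0.13 with an estimated correlation), and Xist lay at 10.1 and 29.4 CPM in CD48dim against 0.676 to 2.56 CPM in the other 6 libraries, while the Y-linked gene Ddx3y lay at 54.0 to 170.8 CPM over the 8 libraries.

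The remaining lists gave these values. The median, mean and test differed in sign for B cell genes in CD48bright against CD48dim (median -0.03, mean 0.43, test upward), and for lymphoid genes (0.02, -0.05, upward) and neutrophil granule genes (0.09, -0.10, upward) in the CD34 comparison. In CD48bright against CD48dim the camera adjusted p was 0.000544 for erythroid genes (median -0.89, adjusted p = 0.31 with an estimated correlation), 0.000544 for basophil, eosinophil and mast cell genes (1.54, 0.13), 0.000382 for T and NK cell genes (3.12, or 2.68 at the bound, 0.167), and 0.0757 for sort marker genes, 0.0772 for neutrophil granule genes, 0.0806 for transcription factors, 0.498 for immediate early genes, 0.561 for B cell genes, 0.498 for macrophage genes and 0.289 for stromal and endothelial genes. In the CD41/CD9 comparison it was 0.00227 for sort marker genes (adjusted p = 0.108 with an estimated correlation), 0.000733 for erythroid genes (0.331), 0.0156 for macrophage genes (0.378), and 0.0509 for DNA replication, 0.135 for interferon, 0.474 for immediate early, 0.213 for mature neutrophil and 0.0735 for stromal and endothelial genes. In the CD34 comparison it was 0.0456 for sort marker genes (adjusted p = 0.197 with an estimated correlation), 0.000382 for platelet genes (0.225), 0.0012 for DNA replication (0.3), 0.00228 for immediate early (0.225), 0.000377 for B cell (0.13), 0.00294 for mature neutrophil genes (0.439), and 0.514 for lymphoid, 0.204 for neutrophil granule, 0.0708 for transcription factors, 0.249 for T and NK cell, 0.126 for macrophage and 0.586 for stromal and endothelial genes.

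Leaving out 1 library ended some of these camera calls or moved their medians. In CD48bright against CD48dim the erythroid call ended without CD48dim replicate 1 (median 0.04), and its median was -1.38 without CD48bright replicate 1. The T and NK cell median went to 6.94 without CD48dim replicate 1 and 2.37 without CD48dim replicate 2. In the CD41/CD9 comparison the sort marker median of -1.47 went to -0.25 without CD48dim replicate 1, and the call ended without CD48dim replicate 2 (-1.28). The macrophage median of -3.01 (-2.29 with 3 genes at their bound) lost its call without CD48dim replicate 1 (-1.89). It was -3.77 without CD34bright replicate 1 and without CD34bright replicate 2, -3.89 without CD48dim replicate 2, -1.69 and -4.05 without CD48bright replicates 1 and 2, and -4.93 without CD41/CD9-negative replicate 1. The erythroid median of -1.03 went to -0.17 without CD48dim replicate 1.

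In the CD34 comparison the sort marker median of 0.27 lost its call without CD34bright replicate 1 (0.41), CD48dim replicate 1 (0.48) or 2 (0.57) and CD48bright replicate 1 (0.80), and was 0.50 without CD34bright replicate 2. The platelet median of -0.76 lost its call without CD34bright replicate 1 (-0.36) and was -1.17 without CD34bright replicate 2. The DNA replication median of 0.36 lost its call without CD34bright replicate 1 (0.12) and was 0.63 without CD34bright replicate 2. The B cell median of -1.82 was -1.12 and -2.77 without CD34bright replicates 1 and 2, and its call ended without CD48dim replicate 1 (-1.58). The mature neutrophil median of -2.55 lost its call without CD48dim replicate 1 (-1.26).

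Other lists passed camera with a library left out or under another setting. In CD48bright against CD48dim these were neutrophil granule genes without CD48dim replicate 1 (median 1.27) or CD48bright replicate 2 (0.95), and sort marker (0.37) and macrophage (1.27) genes without CD48bright replicate 2. In the CD41/CD9 comparison they were stromal and endothelial genes without CD48bright replicate 2 (-2.97), and DNA replication genes without CD34bright replicate 1 (0.22) or 2 (0.23), CD48dim replicate 1 (0.59), CD48bright replicate 1 (0.42) or CD41/CD9-negative replicate 2 (0.44). In the CD34 comparison they were macrophage genes without CD34bright replicate 1 (-0.63), CD48dim replicate 2 (-0.98) or CD48bright replicate 2 (-0.95), neutrophil granule genes without CD34bright replicate 2 (0.37), CD48dim replicate 1 (0.56) or CD48bright replicate 1 (0.59), and transcription factors without CD34bright replicate 2 (-0.32) or CD48bright replicate 2 (-0.43). With the replicate number as a block, neutrophil granule genes (0.49) and transcription factors (-0.22) also passed in CD48bright against CD48dim, and DNA replication genes (0.29) in the CD41/CD9 comparison. Without a count filter, sort marker (0.81) and neutrophil granule (0.45) genes passed in CD48bright against CD48dim, DNA replication genes (0.22) in the CD41/CD9 comparison and transcription factors (-0.37) in the CD34 comparison. DNA replication genes (0.22) also passed in the CD41/CD9 comparison with the DESeq2 size factors, and sort marker genes in CD48bright against CD48dim with fry (adjusted p = 0.0258).

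The lymphoid and dendritic genes that were high in CD41/CD9-negative cells could in part come from admixed cells of another type. Mature cells with much MHC class II would raise a list of 7 such genes, 3 of them (Cd74, H2-Aa, H2-Ab1) also in the monocyte and dendritic list, along with the lymphoid genes, whose median against CD48bright was 2.77. Their median was -0.82 (SD 0.796), with Cd74 at 239.9 and 118.5 CPM against 328.5 and 225.8 CPM in CD48bright. As a set these genes thus did not rise with the lymphoid genes against CD48bright, but H2-DMa (0.78) and H2-DMb1 (0.51) had a positive sign. The median was the value of Ciita (SE 0.91), and 0 of the 7 genes passed. But Cd74 was itself high in CD48bright, against 21.6 and 63.7 CPM in CD34bright and 83.3 and 11.8 CPM in CD48dim. A test against CD48bright therefore cannot exclude such cells. B-lineage cells remain open as a candidate. The 11 B cell genes had a median of 2.76 (SD 1.51) against CD48bright, close to that of the lymphoid list, but only 1 of them passed. Their most abundant member reached only 42.8 CPM (Ebf1), and Vpreb1 lay at 1.34 and 1.62 CPM. The KIT gate would remove mature B cells but not their KIT+ precursors, and lymphoid priming within the population itself was not tested.

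CD48dim replicate 2 correlated with the other 7 libraries at 0.808 to 0.858. Depth does not account for this: with every library thinned to its 7232122 counts, the lowest correlation within the other 3 populations was 0.953. A candidate explanation is that few RNA molecules were copied before the amplification, since 14 of 5797 genes at 20 CPM or more in the other 7 libraries fell below an eighth of that in this one, against 3 of 5409 in CD48dim replicate 1 and 0 in the other 6 libraries taken the same way. That is a small share of the genes, and a difference in the sorted cells, such as the high Malat1 or the mature neutrophil transcripts of replicate 1, was not excluded.

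The absence of calls between CD34bright and CD48bright may in part reflect the spread that the CD48dim libraries add to the shared estimate. Without both CD48dim libraries 12 genes were called for this pair, and the genes at an unadjusted p below 0.05 went from 262 to 619, where chance alone gives 659. An edgeR fit of the CD34bright and CD48bright libraries alone also lacked CD48dim, and called 0 genes, with 588 at an unadjusted p below 0.05. In both fits without CD48dim the genes at an unadjusted p below 0.05 thus rose to near the number that chance gives. The low number in the fit of all 8 libraries therefore went with the CD48dim libraries. The fits without CD48dim differed in calls, and do not settle whether that spread accounts for the absence of calls. Closeness of the 2 populations in expression also stays open and was not tested.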
